A study of Homo sapiens with 3 samples.

How the data were processed

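DNaseI fragments from nuclei of 3 established human cell lines were hybridized to NimbleGen tiling arrays of the ENCODE pilot loci. Per the labels, nuclei of GM06990c, Caco2 or HepG2 were treated with low amounts of DNaseI, small fragments were enriched on sucrose gradients and labelled with Cy5, and DNaseI-fragmented naked DNA was the control. The labels give the Cy5 channel directly and pair Cy3 with a total input protocol, so reading Cy3 as the naked DNA control rests on that pairing. Samples were grouped by the cell line named in the labels, with 1 array in each group, no dye swap and no replicate. No batch could be separated from the cell line.

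Intensities per probe and per channel were deposited by the authors as scanner output with no normalization recorded. Per the file headers, the Caco2 intensities came from NimbleScan 2.1.68 and the HepG2 intensities from NimbleScan 2.2.18, and the GM06990c files carry no header. The authors also deposited a table of log2 ratios per probe. Set against the intensities, each of its columns equalled the log2 of Cy5 over Cy3 plus 1 constant per array, 0.836 for GM06990c, 0.213 for Caco2 and 0.535 for HepG2, within 0.005. This settles its scale, direction and centring. Column medians were 0.01, 0 and 0. How the constants were chosen is not stated, nor why 7494 probes (1.96%) have no value for GM06990c. The GM06990c array is of another design than the other arrays, but all 382884 tiled probes were on each of the 3. Differences between GM06990c and the other lines cannot be told apart from this difference in design.

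The ratio of Cy5 to Cy3 was taken per probe as log2, from the intensities as given, and centred on each array's median over tiled probes, without loess or quantile normalization. Probes were placed by matching their offsets within each locus to the positions of the deposited table. Each window value was the median of the probes within 250 bp of a probe, with at least 5 probes. This gave 368308 windows per array (96.2% of probes), with robust SDs (scaled median absolute deviations) of 0.17, 0.11 and 0.14 in GM06990c, Caco2 and HepG2. The noise of a window, from the difference between its odd and its even probes, had a robust SD of 0.07, 0.08 and 0.08. Spots printed in duplicate (1767 pairs) had an SD of 0.21 on the Caco2 array and 0.26 on the HepG2 array. The threshold of an array was the lowest value at which windows at or below its negative numbered at most 1% of those at or above it. Windows past it within 250 bp of one another were merged. The thresholds rested on 14, 24 and 17 windows on the negative side. Where fewer than 1000 windows passed, the plan named the highest 1% of windows instead. This switch was not applied to GM06990c after loess, where 71 windows passed. Regions overlapping by at least 1 bp were joined into a union set. A region was selective for a line if it was called there and its highest window in each other line stayed below that array's window median plus 1 robust SD.

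Overlap was given as the percent of the smaller set, beside 1000 circular shifts of positions within each locus. Correlations were Pearson's and Spearman's across windows, with percentile intervals from 1000 bootstraps of the loci. The density ratio of a list of loci was its regions per 100 kb over those of all other loci. Percentiles were taken among 10000 random placements of as many probes in the other loci. They were given for the share of probes inside regions and for the median window value. Shares have exact Clopper-Pearson intervals at 95%, and ratios have intervals derived from them. With 1 array per line no test across samples was possible, and the number of arrays limits the precision.

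The thresholds, size rules, lists of loci and most alternatives were fixed before the data were examined. So was the rule for what is named: per line, the 5 highest regions and the 5 selective regions farthest above the other lines, the 5 regions shared by all lines with the highest scaled mean height, and every locus of the fixed lists. Loci outside these lists were named for their density after the values were seen. The lists were the liver and intestine, immune, globin, developmental, epithelial and imprinted loci. The alternatives fixed at that stage were loess within arrays, the deposited log2 table as input, quantile normalization between arrays, windows of 150 or 500 bp to each side, a trimmed mean, omission of the dimmest 10% of probes, background shares of 0.1% or 5%, the highest 1% of windows, other merging gaps, other overlap criteria and other margins of the selectivity rule. Chosen after the data were seen were omission of probes with no value, centring of blocks on the slide, a threshold of 8 robust SD above the window median, and the use of that threshold or the highest 1% for the lists of loci.

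The procedure was tested on simulated arrays over the real 382884 probes, which kept the real low-ratio windows and had regions of 10 probes added. For GM06990c, 0% of regions with a log2 ratio of 1 were recovered, 88.0% of those with 2 and all of those with 3. For Caco2, 93.0% were recovered at 1 and all at 2 and 3. For HepG2, 0% were recovered at 1 and all at 2 and 3. Regions were added only in windows with at least the median number of probes. The simulated arrays gave 0 false regions, but their background was normally distributed noise apart from the real low-ratio windows. Such noise could hardly reach thresholds set by those windows, so false calls on the real arrays were not assessed.

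Signal at promoters and in lists of genes was not computed, because no annotation of the build of the probe coordinates was available and the build is not given in the sources used here; the reference gene table is of GRCh38.p14 and was used for no coordinate. GC content was not checked, since the files hold no probe sequences. Probes outside the tiled loci entered none of the main comparisons and are described only among the results flagged for a closer look. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots used matplotlib 3.10.9.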

Results

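DNaseI hypersensitivity was mapped in 3 human cell lines, GM06990c B lymphocytes, Caco2 colon cells and HepG2 liver cells, to compare where chromatin was open to the enzyme in each. DNaseI is a nuclease that cuts exposed DNA first, and short fragments released by cuts lying close together mark accessible stretches. On each array, fragments released from nuclei (Cy5) were set against the control (Cy3) over 44 tiled loci of the ENCODE pilot set. Reading this control as DNaseI-fragmented naked DNA rests on the pairing described above. All 3 arrays carried the same 382884 tiled probes of 50 bases, spaced 38 bp apart at the median and covering 14.86 Mb. Median tiled-probe intensities were 3113 (Cy3) and 1753 (Cy5) for GM06990c, 2340 and 2069 for Caco2, and 1952 and 1376 for HepG2. With 1 array per line there were no replicates, no difference between lines was tested against biological spread, and the number of arrays limits the precision. Intervals below are exact binomial (Clopper-Pearson) 95% intervals and cover counting error only. They treat regions as independent, although neighbouring regions can be pieces of 1 site, so intervals for densities may be too narrow. Signals are centred log2 ratios of Cy5 over Cy3, as medians over probes within 250 bp, and a probe SD is the spread between the probes of 1 window. Named regions have the bounds of the union set, which can be wider than the call in a single line. The value of each line is its highest window inside those bounds, and these windows can lie at different positions. Positions are those of the deposited files, whose genome build is not given in the sources used here. No region could therefore be placed in an exon, intron or untranslated region, and genes are named only as known contents of the loci.

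The strongest hypersensitive region in B lymphocytes lay in ENm001, the locus holding the chloride channel gene CFTR, the growth factor receptor gene MET and the caveolin genes CAV1 and CAV2. On chromosome 7 from 116203836 to 116205975, its highest window reached a log2 ratio of 4.36 (20.6-fold, probe SD 0.59, 13 probes). A neighbouring region, from 116206192 to 116206849, reached 3.77. In the former, the highest windows were 0.16 in Caco2 and 0.05 in HepG2. The highest region in Caco2 lay in ENm007 on chromosome 19 from 59332373 to 59333220, with a log2 ratio of 2.60 (6.07-fold, probe SD 0.54). ENm007 includes the LILR and KIR immune receptor genes, but the region could not be assigned to any gene. The highest region in HepG2 lay in ENr311 on chromosome 14 from 52069828 to 52071131, with a log2 ratio of 3.28 (9.73-fold, probe SD 1.02). Both were called in all 3 lines.

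Other high regions in B lymphocytes lay in ENr333 (3.94, chromosome 20 from 35044712 to 35046585), ENr212 (3.84, chromosome 5 from 142410498 to 142411839) and ENr324 (3.75, chromosome X from 121793456 to 121794949). The ENr333 and ENr324 regions were called in all lines, whereas the ENr212 region read 0.19 in Caco2 and 0.18 in HepG2. In Caco2 the next regions were in ENm005 (2.58, chromosome 21 from 33496417 to 33496998), ENm007 (2.51, chromosome 19 from 59666773 to 59667544), ENm001 (2.49, chromosome 7 from 116877234 to 116878195) and ENm013 (2.48, chromosome 7 from 89587580 to 89588617). ENm005 holds the interferon receptor genes IFNAR1, IFNAR2 and IFNGR2 with the interleukin 10 receptor gene IL10RB. In HepG2 they were in ENm005 (3.20, chromosome 21 from 33933873 to 33935138), ENm007 (3.11, the same region that ranked highest in Caco2), ENr333 (2.95, the region also high in B lymphocytes) and ENr222 (2.82, chromosome 6 from 132196481 to 132197138). The ENr222 region reached 1.56 in Caco2 and 0.11 in GM06990c.

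Across the tiled loci, 162 regions were called in GM06990c, 268 in Caco2 and 168 in HepG2. They lay in 31, 36 and 32 of the 44 loci. Median widths were 316 bp in GM06990c, 316 bp in Caco2 and 373 bp in HepG2, and median heights were 2.18, 1.10 and 1.71 on the log2 scale. The threshold that each array set for itself differed: a log2 ratio of 1.80 (3.49-fold) for GM06990c, 0.79 (1.72-fold) for Caco2 and 1.27 (2.41-fold) for HepG2. The order of the lines by number of regions was not stable. With a threshold of 8 robust SD on each array the counts were 345, 244 and 224, and with quantile normalization 114, 202 and 295. After loess normalization GM06990c had 10 regions, all overlapping those called without it, while HepG2 had 338. Only 71 GM06990c windows passed after loess, at a threshold of 2.70, too few for the planned rule. The planned switch to the highest 1% of windows was not applied there, so GM06990c values after loess hold for that threshold only.

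**Figure D1:**
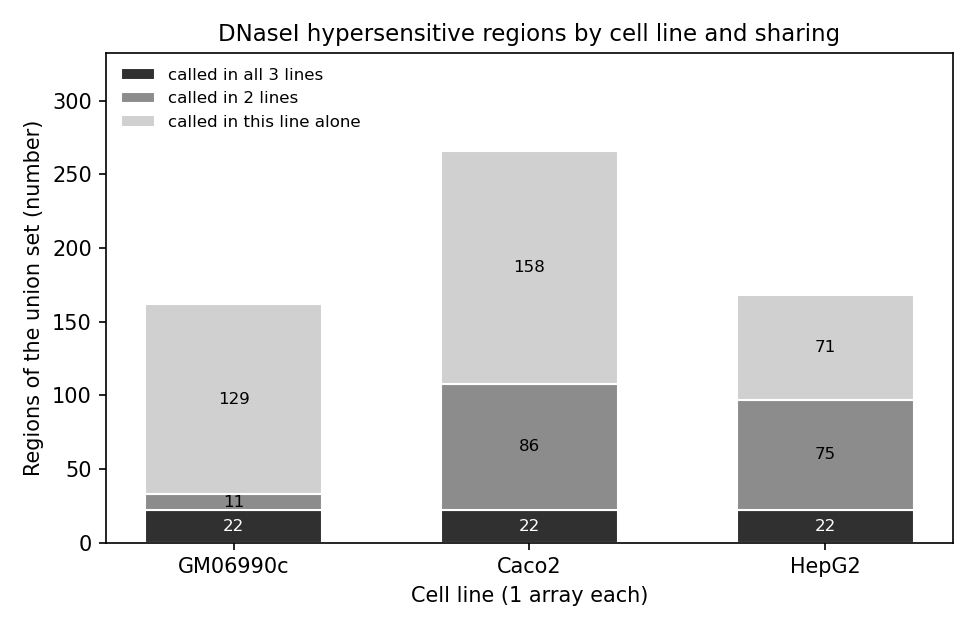
Stacked bars give the number of union regions called in each cell line (1 array each), split by how many lines shared the call. Regions called in a single line numbered 129 in GM06990c, 158 in Caco2 and 71 in HepG2, and 22 were called in all 3.

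Sharing between the lines asks which open regions are common to unrelated cell types. The regions shared most strongly were in ENr333, in ENm007 and ENm005, and in ENr231. The ENm007 region at 59332373 read 2.65 in GM06990c, 2.60 in Caco2 and 3.11 in HepG2. The second ENm007 region, at 59666773, read 2.60, 2.51 and 2.77 in the same order. The ENm005 region at 33933873 read 2.86, 2.39 and 3.20, the ENr333 region at 35044712 read 3.94, 2.12 and 2.95, and the ENr231 region on chromosome 1 from 148470251 to 148471326 read 2.38, 1.93 and 2.68. Joined by overlap, the called regions formed 466 union regions, of which 22 (4.72%) were called in all lines, 86 in a pair of lines and 358 (76.8%) in a single line. Of the 86, 75 joined Caco2 with HepG2, 11 joined GM06990c with Caco2, and 0 joined GM06990c with HepG2 alone. The count shared by all lines was 2 after loess, 13 with windows of 500 bp to each side, 36 with a background share of 5%, 44 at 8 robust SD and 54 with the highest 1% of windows, and the union reached 1407 regions with a background share of 5%.

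Caco2 and HepG2 shared the most called regions. Their arrays also had the same number of probes (388468), while GM06990c was on another design (385302 probes). Cell type and array design cannot be told apart in this comparison. Of the 168 HepG2 regions, 97 (57.7%, interval 49.9% to 65.3%) overlapped a Caco2 region. Of the 162 GM06990c regions, 32 (19.8%, interval 13.9% to 26.7%) overlapped a Caco2 region and 21 (13.0%, interval 8.21% to 19.1%) overlapped a HepG2 region. Shifting regions around each locus 1000 times gave medians of 2.38%, 1.85% and 1.23% for these pairs, with a highest value of 8.93%. Some regions called in a single line carried weaker signal elsewhere. Of the 71 called in HepG2 alone, 48 (67.6%) reached at least 3 robust SD above the window median in Caco2, and 31 (43.7%) did so in GM06990c. Of the 158 called in Caco2 alone, 84 (53.2%) did so in HepG2 and 51 (32.3%) in GM06990c. Of the 129 called in GM06990c alone, 28 (21.7%) did so in Caco2 and 17 (13.2%) in HepG2. Pearson's r across 368308 windows was 0.470 for Caco2 with HepG2 (0.410 to 0.522 over 1000 bootstraps of loci), 0.320 for GM06990c with Caco2 (0.262 to 0.378) and 0.317 for GM06990c with HepG2 (0.244 to 0.391). Spearman's rho, which weighs the many windows near background, had another order, with 0.190, 0.260 and 0.284 for these pairs. Pearson's r over single probes, at 0.194, 0.160 and 0.230, was also highest for GM06990c with HepG2. Windows overlap and are not independent replicates. Within an array, window medians of odd-numbered probes and of even-numbered probes correlated at 0.893 in GM06990c, 0.613 in Caco2 and 0.726 in HepG2. These values are of windows and are not comparable with those over single probes. With a background share of 5%, which lowered the Caco2 threshold most, 39.4% of GM06990c regions overlapped a Caco2 region, and the overlap of GM06990c with HepG2 reached 24.6% under a threshold of 8 robust SD.

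Regions selective for a line were sought as candidates for cell-type regulation. Of the 5 selective B lymphocyte regions farthest above the other lines, 1 lay in ENm014 and 2 in ENm002. ENm014 holds GRM8, a glutamate receptor gene, and ENm002 holds the interleukin genes IL3, IL4, IL5 and IL13 with CSF2 and IRF1. The ENm014 region on chromosome 7 from 125896143 to 125896382 read 3.24 in GM06990c (9.46-fold, probe SD 0.83, 6 probes), 0.09 in Caco2 and -0.11 in HepG2. The ENm002 regions on chromosome 5, from 132162855 to 132163474 and from 131510395 to 131510786, read 2.74 and 2.66 in GM06990c, 0.07 and 0.07 in Caco2, and -0.08 and -0.09 in HepG2. Further GM06990c regions in ENr232 (chromosome 9 from 127409123 to 127409552) and ENm013 (chromosome 7 from 90173730 to 90173931) reached 2.67 and 2.62.

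The leading Caco2-selective region was in the CFTR and MET locus ENm001, on chromosome 7 from 116877234 to 116878195. It read 2.49 in Caco2 (5.63-fold, probe SD 0.97, 9 probes), 0.07 in GM06990c and 0.10 in HepG2. By distance above the other lines, next came regions in ENr111 (1.76, chromosome 13 from 28444176 to 28445137), ENr333 (1.56, chromosome 20 from 34622380 to 34623075), ENr321 (1.29, chromosome 8 from 118939944 to 118940069) and ENm003 (1.32, chromosome 11 from 116100018 to 116100257). ENm003 holds the apolipoprotein genes APOA1, APOC3, APOA4 and APOA5, whose products carry lipids in plasma. The leading HepG2-selective region lay in ENr334 on chromosome 6 from 41761898 to 41762289 and read 2.11 in HepG2 (4.33-fold, probe SD 0.56, 7 probes), -0.22 in GM06990c and 0.04 in Caco2. The next HepG2 regions by the same distance were in ENm002 (1.73, chromosome 5 at 131409049), ENm013 (1.51, chromosome 7 from 89648570 to 89648847), ENr334 (1.27, chromosome 6 at 41783292) and ENr212 (1.28, chromosome 5 at 142304364). The ENm002, ENr212 and second ENr334 calls each rested on 1 window.

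**Figure D2:**
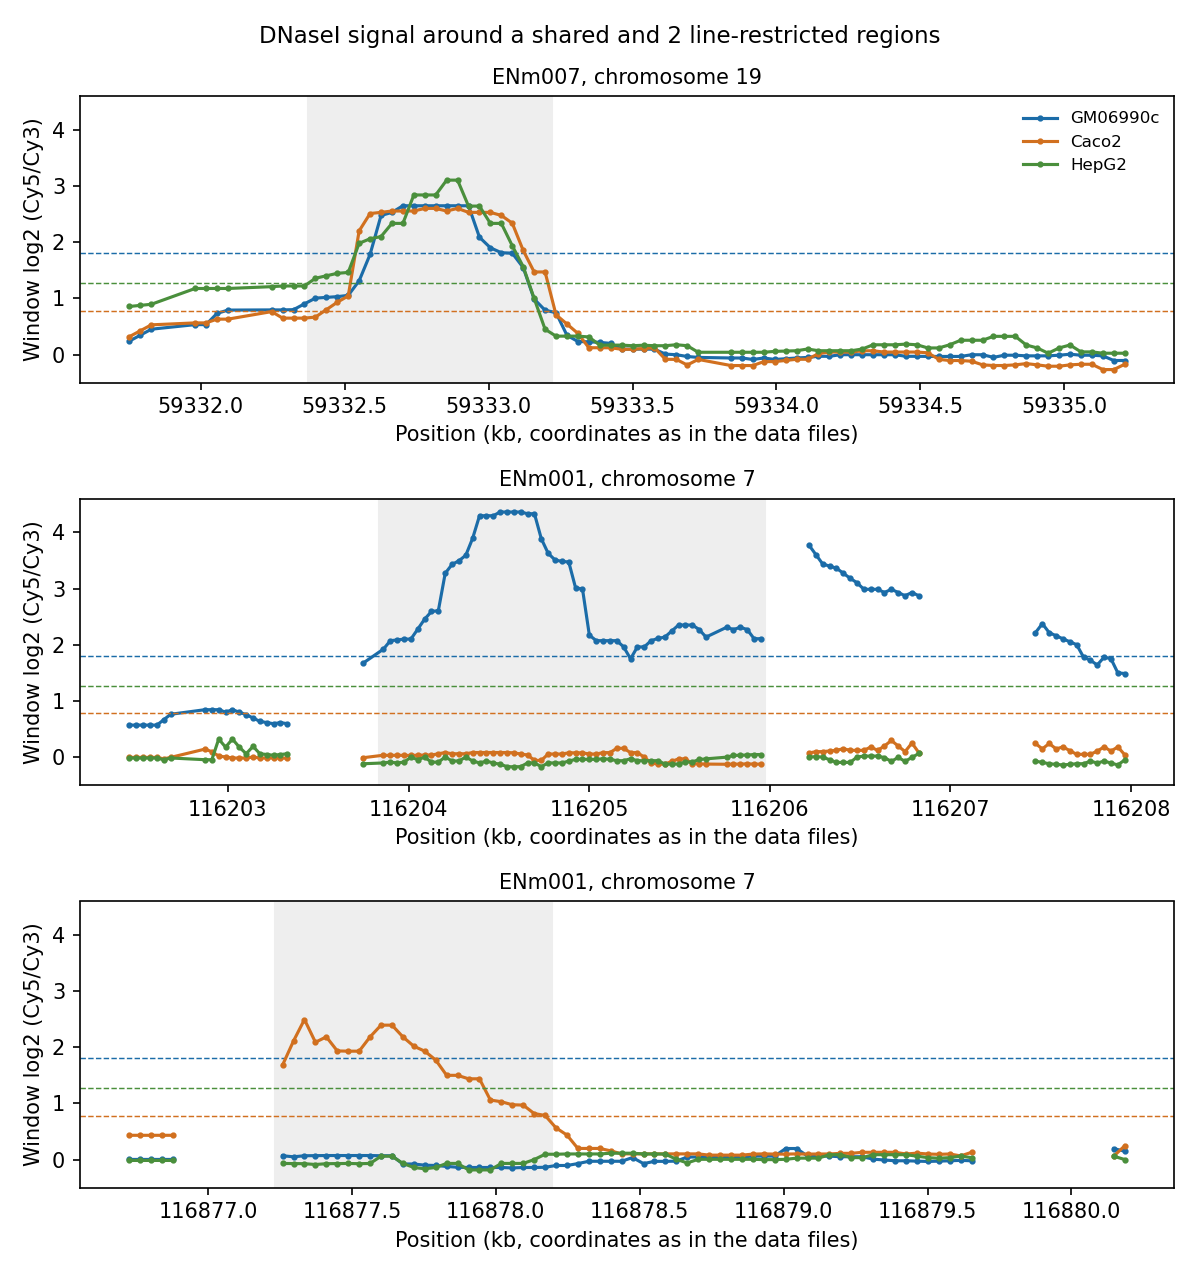
Window log2 ratios (y axis) are drawn against position in kb (x axis) around a shared region of ENm007 and regions of ENm001 called in GM06990c alone and in Caco2 alone; lines break where probes are missing, dashed lines are each array's threshold and grey marks the region. The peaks reach 2.65, 2.60 and 3.11 in GM06990c, Caco2 and HepG2 in the first panel, 4.36 in GM06990c in the next and 2.49 in Caco2 in the last.

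By the size rule, 43 GM06990c regions (26.5% of those called there), 30 Caco2 regions (11.3% of 266 union regions called there) and 6 HepG2 regions (3.57%) were selective. Those of GM06990c were spread over 23 loci, with 4 each in ENm002, ENm005 and ENr111. Of the 30 in Caco2, 8 lay in ENm001, 4 in ENr321 and 3 in ENr323. Loess normalization, which left only 10 regions in GM06990c, turned the order to 3 selective regions there, 18 in Caco2 and 22 in HepG2. A background share of 5% put Caco2 first with 289. With other lines allowed up to 2 robust SD the counts were 81, 50 and 12, with others below the window median they were 8, 4 and 1, and at 8 robust SD GM06990c had 81. The rule is strict. Of 50 simulated single-line regions with a log2 ratio of 3, it named 25 for GM06990c, 30 for Caco2 and 23 for HepG2. It takes the highest of all windows in a region, and the simulated regions were all 10 probes long. Its dependence on region width was therefore not tested.

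The immune loci ENm002, ENm005 and ENm007 carried more regions than the rest of the tiled sequence in every line. The ratio was largest in B lymphocytes, but the intervals of the lines overlapped. Some of these regions were called in all lines, such as those at 59332373 and 59666773 in ENm007 and 33933873 in ENm005. No region could be assigned to a gene, so the ratios do not show that regions lay at immune genes. GM06990c had 39 regions there, or 2.24 per 100 kb against 0.938 elsewhere, a density ratio of 2.38 (interval 1.62 to 3.44). The ratio was 1.477 (1.04 to 2.05) in Caco2 and 1.84 (1.22 to 2.71) in HepG2. The interferon receptor locus ENm005 alone held 20 regions in GM06990c, 23 in Caco2 and 11 in HepG2, with ratios of 2.40, 1.60 and 1.20. In ENm002 and ENm007 the ratio was larger in HepG2 (2.06 and 2.33) than in GM06990c (1.94 and 1.96). Both of these GM06990c intervals included 1 (0.911 to 3.66 and 0.877 to 3.81). Among 10000 random placements, the share of immune probes inside regions ranked at percentile 99.1 in GM06990c, 73.3 in Caco2 and 93.4 in HepG2. The median window value of these loci ranked lower, at percentiles 44.1, 7.52 and 23.3 in the same order. After loess the GM06990c ratio was 0.836, on 10 regions.

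The developmental loci ENm010, ENm012 and ENm014 differed between lines and among themselves. ENm010, which holds the HOXA genes for body patterning, had 0 regions in GM06990c, 8 in Caco2 and 3 in HepG2. ENm012, which holds the forkhead factor gene FOXP2, had 9 regions in GM06990c, 1 in Caco2 and 0 in HepG2, and ENm014 had 5, 1 and 0. Many of the GM06990c regions lay close together, between 114110342 and 114127795 in ENm012 and between 125893749 and 125896382 in ENm014. These counts may therefore exceed the number of separate sites. Together the 3 loci had density ratios of 0.857 (0.458 to 1.485) in GM06990c, 0.351 (0.167 to 0.657) in Caco2 and 0.165 (0.0336 to 0.490) in HepG2, at percentiles 56.1, 7.98 and 4.79 for the share of probes inside regions. By median window value these loci ranked high instead, at percentiles 100, 100 and 95.95 in GM06990c, Caco2 and HepG2. Their GM06990c density ratio was 2.27 after loess, which left only 10 regions in all loci of that line. With windows of 500 bp to each side, the Caco2 ratio was 0.126 and HepG2 had 0 regions there.

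Loci of liver and intestine genes were ENm003, ENr131 with the UGT1A genes for glucuronidation, and ENr132 with the coagulation factor gene F7. Their combined density ratios were 0.998 (0.448 to 1.94) in GM06990c, 1.37 (0.821 to 2.16) in Caco2 and 1.79 (0.995 to 2.99) in HepG2, all intervals including 1. The percentiles for the share of probes inside regions were 60.9, 67.3 and 63.5. Those for the median window value were low, at 0, 7.08 and 0.54. The apolipoprotein locus ENm003 had 6 regions in GM06990c, 13 in Caco2 and 5 in HepG2, and its Caco2 ratio was 3.09 (1.62 to 5.38). The F7 locus ENr132 had 3, 6 and 8 regions, and the UGT1A locus ENr131 had 0, 1 and 3. The epithelial locus ENm001 had 18 regions in GM06990c, 24 in Caco2 and 5 in HepG2, with ratios of 1.71 (0.983 to 2.79), 1.34 (0.843 to 2.04) and 0.418 (0.134 to 0.997) at percentiles 93.0, 70.1 and 38.2. By median window value ENm001 ranked at percentiles 94.5, 92.8 and 91.1 in GM06990c, Caco2 and HepG2. Its Caco2 ratio fell below 1, to 0.791, with windows of 500 bp to each side. Its GM06990c ratio was 3.41 after loess, which left only 10 regions in all loci of that line.

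The globin loci, ENm008 with the alpha and ENm009 with the beta globin genes of red blood cells, held at most 3 regions each in any line. The beta globin locus ENm009 had 0 regions in GM06990c, 3 in Caco2 (ratio 0.313, 0.0641 to 0.924) and 1 in HepG2 (ratio 0.166, 0.0042 to 0.935). The alpha globin locus ENm008 had 0, 3 (ratio 0.627, 0.129 to 1.85) and 3 (ratio 1.01, 0.206 to 2.996). Together, GM06990c had 0 there, which allows a density ratio of up to 0.414, while Caco2 had 6 (ratio 0.412, 0.150 to 0.909) and HepG2 had 4 (ratio 0.439, 0.118 to 1.15). Percentiles for the share of probes inside regions were 0, 18.1 and 20.2. Those for the median window value were 49.2, 46.7 and 22.0. The imprinted locus ENm011, with IGF2 and H19, had 0 regions in GM06990c (ratio up to 0.872), 1 in Caco2 (ratio 0.142, 0.0036 to 0.797) and 2 in HepG2 (ratio 0.456, 0.0548 to 1.67), at percentiles 0, 15.5 and 26.4. For ENm011 the percentiles by median window value were 23.1, 2.99 and 44.3. With the highest 1% of windows GM06990c had regions in the globin loci, at a ratio of 0.347. The single Caco2 call in ENm011 was lost after loess and with windows of 500 bp to each side.

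Among the other loci, ENr111, ENr231 and ENr333 stood out for density. ENr111 was densest in GM06990c, with 10 regions (4.35 per 100 kb), against 7 in Caco2 and 0 in HepG2. In Caco2 ENr333, with 21 regions (9.24 per 100 kb), and ENr231, with 19 (9.17 per 100 kb), were close. With the highest 1% of windows their order turned, to 10.57 in ENr333 and 10.62 in ENr231. ENr333 had 2 regions in GM06990c and 7 in HepG2. ENr231 was densest in HepG2, with 8 regions (3.86 per 100 kb), and held 7 in GM06990c. ENr122 and ENr123 each had 5 regions in GM06990c and 0 in both other lines, and ENr112, ENr113, ENr114, ENr211 and ENr312 had 0 in any line. With the highest 1% of windows, HepG2 had 2 regions in ENr111 and 1 in ENr123, Caco2 had 1 in ENr122 and 1 in ENr114, and ENr112, ENr113, ENr211 and ENr312 still had 0.

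**Figure D3:**
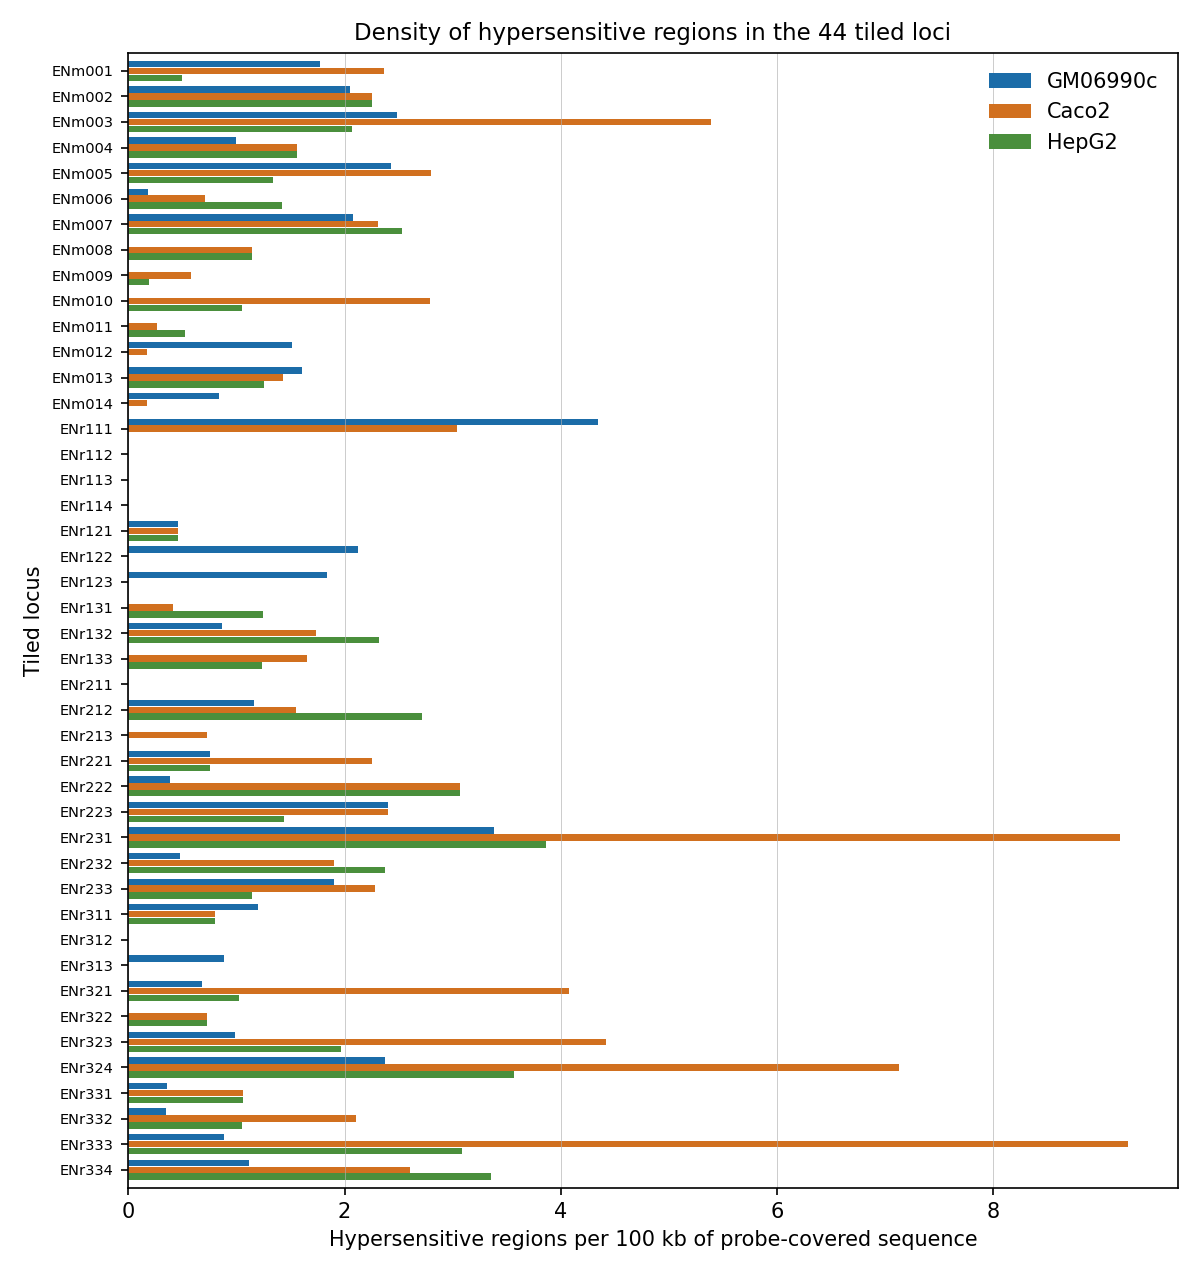
Bars give hypersensitive regions per 100 kb of probe-covered sequence (x axis) in each of the 44 tiled loci (y axis) for the 3 cell lines, 1 array each. The highest bars are 9.24 in ENr333 for Caco2, 4.35 in ENr111 for GM06990c and 3.86 in ENr231 for HepG2.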

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

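No difference in this part was tested, since each line has 1 array, and the look at probes outside the tiled loci was chosen only after their presence was seen.

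The GM06990c array also tiled a stretch of chromosome 16, from 10924000 to 10944000, named after CIITA, the master regulator gene of MHC class II expression. Of its 525 windows, 75 (14.3%) passed the GM06990c threshold, against 0.454% in the tiled loci. This drew attention because the main comparisons did not use those probes. They formed 4 regions, starting near 10929320, 10930726, 10936654 and 10941632 (exact to 1 bp), with heights of 2.34, 2.77, 2.43 and 1.83. The regions held 85 probes, fewer than the 113 in the richest stretch of as many probes in the tiled loci. The Caco2 and HepG2 arrays lacked these probes, so no line can be set beside GM06990c here, and no explanation was tested.

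All 3 arrays also carried 31 control sequences whose identities the files do not give. Windows past the threshold occurred in 9 of them in GM06990c, 11 in Caco2 and 12 in HepG2, and 6 passed in every line. The main comparisons did not use these probes.

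Some leading selective regions had a window below the background median, by more than 1 robust SD, in another line at the summit position. This held for 6 of 30 readings, over regions picked for low values in the other lines. By line, it held for 2 of 10 readings in GM06990c, 0 of 10 in Caco2 and 4 of 10 in HepG2. Of all windows, 13.7% in GM06990c, 14.2% in Caco2 and 17.0% in HepG2 lie over 1 robust SD below the median. The lowest readings were rarer, with 2.31% of GM06990c windows at or below -0.35 and 3.60% of HepG2 windows at or below -0.30. At the GM06990c-selective regions of ENm002, HepG2 read -0.16 at 132162855 and -0.14 at 131510395. At the Caco2-selective region of ENr321, HepG2 read -0.30. At the Caco2-selective region of ENm003, in the apolipoprotein locus, GM06990c read -0.30 and HepG2 read -0.20. At the HepG2-selective region of ENr334, GM06990c read -0.35. These differences were not tested.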

How the results depend on the processing

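Omission of probes with no value and the threshold of 8 robust SD were chosen only after the data were seen. No paired analysis was possible because each cell line has 1 array and the labels carry no replicate numbers that could pair them. No direction reversed for the correlations or for the named regions, but the latter were picked for large values. Some density ratios crossed 1 after loess or with wider windows, as given below. Caco2 with HepG2, the pair without the other array design, had the highest overlap at every setting, from 45.3% to 82.5%. The array thresholds, set by few low-ratio windows, limited which regions could be seen: weaker ones fell below them in GM06990c and HepG2. Of the values for named regions under the alternatives, 292 stayed within 1 SD between the probes of the window and 21 did not, 11 of these with windows of 500 bp to each side. The alternatives for promoter signal and gene lists were not run, for want of an annotation. For all values below the cause was not tested. The GM06990c values after loess rest on 71 windows, without the planned switch to the highest 1% of windows.

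Loess gave 10 regions in GM06990c, in 8 loci, and 338 in HepG2, with 2 called in all lines; selective regions were 3 in GM06990c, 18 in Caco2 and 22 in HepG2, the overlap of GM06990c with HepG2 was 20.0%, GM06990c density ratios were 0.836 (immune), 2.27 (developmental) and 3.41 (epithelial), and the imprinted ratio in Caco2 was 0. Quantile normalization gave HepG2 295 regions, 16 of them selective, and an overlap of GM06990c with HepG2 of 22.8%. Windows of 150 bp to each side gave Caco2 445 regions and 54 selective ones. Windows of 500 bp gave 146 regions in Caco2 (13 selective), 106 in HepG2 (2 selective), 13 in all lines and 291 in the union, an overlap of Caco2 with HepG2 of 45.3%, Caco2 ratios of 0.126 (developmental), 0.791 (epithelial) and 0 (imprinted), and a HepG2 developmental ratio of 0. The trimmed mean gave an overlap of Caco2 with HepG2 of 66.5%.

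A background share of 0.1% gave 3 selective regions in HepG2. A share of 5% gave Caco2 1253 regions (289 selective), HepG2 11 selective regions, 36 in all lines and 1407 in the union, with overlaps of 39.4% (GM06990c with Caco2), 19.7% (GM06990c with HepG2) and 82.5% (Caco2 with HepG2). The highest 1% of windows gave GM06990c 317 regions (73 selective), Caco2 52 selective, HepG2 330 (21 selective), 54 in all lines, 773 in the union and an overlap of GM06990c with HepG2 of 20.5%. Omission of probes with no value gave Caco2 52 selective regions and an overlap with HepG2 of 66.7%. The threshold of 8 robust SD gave GM06990c 345 regions (81 selective), 44 in all lines and an overlap of GM06990c with HepG2 of 24.6%. A margin of 2 robust SD gave 81, 50 and 12 selective regions in GM06990c, Caco2 and HepG2, and a margin at the window median gave 8, 4 and 1.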

Other observations

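The tests of repeated sequence and of thresholds, and the grouping by gene density, were chosen only after the results were seen.

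The randomly chosen loci (ENr) were picked for the pilot set by gene density and by conservation outside exons, low, middle or high, with 10 loci in each class of gene density. In HepG2, regions averaged 0.352 per 100 kb (SD 0.869 over 10 loci) in loci of low gene density, 1.30 (SD 1.22) in the middle class and 2.07 (SD 1.07) in the high class. In Caco2 the averages were 0.613 (SD 1.01), 2.45 (SD 2.30) and 3.22 (SD 3.22). In GM06990c they were 0.760 (SD 1.36), 1.20 (SD 0.898) and 0.933 (SD 1.03). At least 1 region was called in 10 of 10 high-density loci in both Caco2 and HepG2 and in 8 of 10 in GM06990c, against 4, 2 and 4 of the low-density loci in Caco2, HepG2 and GM06990c. By conservation, the averages in low, middle and high classes were 0.730, 2.59 and 2.92 in Caco2, 0.525, 1.71 and 1.51 in HepG2, and 0.963, 1.16 and 0.802 in GM06990c.

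The difference between high and low classes of gene density was 0.173 per 100 kb (SE 0.541) in GM06990c, within its spread, 2.60 (SE 1.07) in Caco2 and 1.72 (SE 0.436) in HepG2. ENr111, a locus of low gene density, held 4.35 regions per 100 kb in GM06990c. With the highest 1% of windows the GM06990c averages were 1.30 in low and 2.31 in high classes.

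Regions shared by the lines could arise from probes with a fixed dye bias or from chance placement. Windows built from odd probes in one line and even probes in another kept at least 96.3% of the correlation between windows of the same probes, which argues against bias of single probes. The highest overlap among the shifts of all pairs was 8.93%, below each observed overlap, which argues against chance placement within the loci. Open regions common to these cell types remain a hypothesis, since sequence features wider than 1 probe were not tested.

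The larger number of regions in Caco2 may come from stricter thresholds on the other arrays. Under the thresholds of each array, Caco2 had 1.65 times the regions of GM06990c and 1.60 times those of HepG2. With an equal share of windows on each array, Caco2 had at most 1.22 times the regions of another line. That setting takes 3684, 3685 and 3686 windows in GM06990c, Caco2 and HepG2, which brings the counts close whatever the cause. It therefore cannot tell stricter thresholds from a real excess in Caco2. A difference in open chromatin between the cell types was not tested, and line and array cannot be separated with 1 array each.

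Low ratios on all 3 arrays marked 7 stretches with 257 probes, the longest in ENm007 on chromosome 19 from 59114519 to 59120724 (6206 bp) and the next in ENr132 on chromosome 13 from 111464963 to 111467254. Median ratios there were -1.63 in GM06990c, -0.44 in Caco2 and -0.97 in HepG2, and in stretches defined on the other arrays alone they were -1.60, -0.17 and -0.88. All 14 and 24 windows that set the thresholds of GM06990c and Caco2, and 15 of the 17 of HepG2, lay in the 7 stretches. Compression of bright signals is argued against in GM06990c and Caco2, where other probes matched on brightness had medians of 0.11 (SD 1.11) and 0.08 (SD 0.32). In HepG2 the matched median was -0.36 (SD 0.60), closest to the stretches, so compression may hold for a part of the low ratio there. Matching used the mean of both colours, so matched probes may be bright in Cy5 rather than Cy3. For sequence present in several copies the values do not decide: in stretches defined on the other arrays, Cy5 was at least 2.59 times the array median, but Cy3 was raised more (7.53, 3.72 and 12.9 times against 2.59, 2.88 and 6.64 for Cy5 in GM06990c, Caco2 and HepG2). Copies alone would raise both colours alike, and picking low ratios favours high Cy3. Of the probes in those stretches, 44.2% to 58.0% had no value in the GM06990c column against 1.96% overall. No alignment of the probes was possible to count copies, and closed chromatin in all lines stays untested.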
